A study of Mus musculus with 6 samples.

How the data were processed

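The 6 samples were total RNA from 3 mouse cell lines, each unstimulated and after 4 h of IFN-β, labelled with an Affymetrix whole-transcript kit per the labels' protocols and hybridised to 1 array each. The deposited values are on the log2 scale and were made by the authors with RMA (background correction, normalization between arrays and a summary per probe set), per the submitters' processing notes. The version and settings of RMA are not given in the sources used here. The log base was read from the values, which run from about 1 to 15 as RMA gives on the log2 scale. The columns had close but not identical distributions, so that a level can shift slightly between arrays, most of all on the stimulated NIH3T3 array. All 6 columns were used, and each was assigned to its group by the sample's title and source.

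The array annotation names a single gene for 21789 of the 35557 probe sets, several genes for 1621 and none for 12147. Genes were analysed through the probe sets of a single gene, with symbols updated by Entrez ID, which matched for all but 91 probe sets and changed 0 symbols. For the 999 genes with several such probe sets the one with the highest mean over the arrays was kept, giving 19938 genes. Genes measured only by probe sets of several genes were not analysed here by name. No filter on low levels was applied. No coordinates are given, because the annotation build of the array is not given in the sources used here.

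Within a line the change is the difference of 2 arrays, with no test, counted at 3-fold as in the series' design text. Across lines, limma 3.58.1 in R 4.3.3 fitted cell line as a block plus treatment with empirical Bayes (2 residual degrees of freedom, prior 7.87), with Benjamini-Hochberg adjustment over the 19938 genes. Stimulated and unstimulated arrays of a line are a pair by the cell line they share. The lines stand in for replicates. Empirical Bayes draws each gene's spread between these 3 lines toward that of all genes. The SEs and p-values of genes whose response varied most between the lines therefore understate their own spread. The difference of RAW264.7 from the fibroblast lines was an interaction term in the same package (1 residual degree of freedom, infinite prior, hence 1 variance for all genes). Gene lists were tested with camera at a preset correlation of 0.01 and again with an estimated one, and within a line by the percentile of the list's median among 10000 random lists of the same size drawn within 20 bins of mean expression. Levels and overlaps were compared as values. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 did the remaining work.

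The tests, the 23 gene lists (354 entries, 303 distinct genes measured), the other settings tried and the rule for naming genes were fixed before the data were examined. The rule named the 15 largest mean increases and 10 largest decreases among genes with an adjusted p under 0.05 and the same sign in all lines; the 10 largest increases and 5 largest decreases of at least 3-fold within each line; the 8 largest differences in each direction for RAW264.7; the 3 members of each list with the largest mean change and the one with the widest range; and the 4 members with the highest level for the marker and housekeeping lists. Genes named outside it were chosen after their values were seen: Eif2ak2, Gbp8, Ifnar1, Ifnar2, Trim25 and, in the closing section, those given there.

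The limma and camera steps were tested on simulated data, with variances drawn from the distribution limma fitted to these arrays. Simulated genes changed by the same amount in each line, or in RAW264.7 alone for the interaction. The rates below therefore do not cover genes whose response differs between lines, such as Ifit1, with an SD between lines of 2.07. With 200 of 19938 genes changed, the test across lines recovered 72% of genes changed by 1 on the log2 scale and 100% of those changed by 2, with 12 false calls beside 186 true ones. The interaction test recovered 0% at 1, 24% at 2, 96% at 3 and 100% at 5, with 4 false calls beside 110 true ones. With camera the 1 shifted list was called and 0 of 20 unshifted lists. Simulated genes varied independently of each other, so false calls from correlation within a list could not appear. In the real data that correlation was estimated at 0.70 for the guanylate-binding proteins. Alternatives covered the probe set chosen per gene, all probe sets, a filter at the median level of 4.82, thresholds of 2-fold and 5-fold, median centring, quantile normalization, empirical Bayes with a trend and robustly, the model without the block, each line left out, an adjusted p under 0.1 and an estimated correlation.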

Results

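Transcript levels were measured on 6 whole-transcript mouse arrays, 1 for each combination of 3 established cell lines and 2 conditions. NIH3T3 is an embryonic fibroblast line, L929 a connective tissue fibroblast line, and RAW264.7 a macrophage line that the labels name as such. Each line was left unstimulated or stimulated for 4 h with interferon-beta (IFN-β), a type I interferon. The series' stated aim was to find genes whose transcription is regulated by IFN-β. No group had a replicate, so differences within a line have no error estimate, and the 3 lines serve as the replicates of the IFN-β effect where a test was made. The number of arrays limits the precision of every value. Median log2 levels lay between 4.72 and 4.82 on 5 arrays and at 5.05 on the array of stimulated NIH3T3, which also had the narrowest interquartile range, 3.46. Over the 19938 measured genes the median log2 change was 0.17 in NIH3T3, -0.05 in L929 and -0.03 in RAW264.7, and changes in NIH3T3 are to be read against that shift.

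The unstimulated arrays were first compared for markers of cell type. Macrophage markers were high in RAW264.7, where Lyz2, a lysozyme, had a log2 level of 12.07 against 3.58 in NIH3T3 and 5.08 in L929. Tyrobp, a signalling adaptor of myeloid cells, was at 11.61 in RAW264.7 against 4.61 and 4.33, Fcer1g, an Fc receptor subunit, at 11.40 against 4.88 and 4.21, and the lysosomal protein gene Cd68 at 11.05 against 6.02 and 4.93. The median of the 17 macrophage markers was 9.11 in RAW264.7, 3.76 in NIH3T3 and 4.08 in L929. Fibroblast markers went the other way, with type I collagen Col1a1 at 11.60 in NIH3T3, 11.32 in L929 and 6.17 in RAW264.7, Col1a2 at 11.36, 11.50 and 5.37, and the matrix protein gene Sparc at 10.84, 11.09 and 4.69. S100a4 was less separated, at 10.56, 11.20 and 9.61. Medians of the 17 fibroblast markers were 10.45, 7.82 and 4.59 in the same order. Epithelial markers, among them Cldn3, Krt8, Cldn4 and Krt18, had medians between 4.53 and 4.65, and lymphocyte markers, among them Cd3e, Cd8a, Cd79b and Cd3g, between 3.63 and 3.95. These differences were not tested, since each line had 1 unstimulated array.

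Several lists of interferon-induced genes already had a higher level in unstimulated RAW264.7 than in the fibroblast lines. The median of the 21 antiviral effectors was 6.63 in RAW264.7, 5.36 in NIH3T3 and 5.14 in L929, and that of the 17 nucleic acid and pathogen sensors was 7.06, 5.23 and 4.84. For the 7 Schlafen genes it was 7.06, 4.31 and 4.89. Guanylate-binding proteins began at similar levels, with medians of 4.05, 3.64 and 3.72.

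The effect of IFN-β common to the lines was tested over the 3 pairs of arrays. IFN-β raised a set of antiviral, chemokine and GTPase genes in all 3 lines. Ifit1 (probe set 10462623), whose product binds viral RNA, rose by a mean log2 change of 6.33 ± 0.56 (SE, n = 3 lines), 80.4-fold, with a limma adjusted p of 0.000489. Cxcl10 (10531415), a chemokine for T cells, rose by 6.20 ± 0.45 (adjusted p = 0.000129), and Iigp1 (10455961), an immunity-related GTPase, by 6.20 ± 0.55 (adjusted p = 0.000489). These SEs are limma's, drawn toward the spread of all genes. The SD of the change between the 3 lines was 2.07 for Ifit1, 1.62 for Cxcl10 and 2.02 for Iigp1. Ifit3 rose by 6.01, Gbp3, a guanylate-binding protein, by 5.68, Usp18, which removes ISG15 from proteins and dampens interferon signalling, by 5.56, and Rsad2, the antiviral enzyme viperin, by 5.44. The other genes among the 15 with the largest mean increase were Ifit3b, Ifi205, Gbp7, Gm4951, Mx2, Gm12250, Oasl2 and Mx1, with mean log2 changes from 5.95 for Ifit3b down to 4.69 for Mx1.

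**Figure D1:**
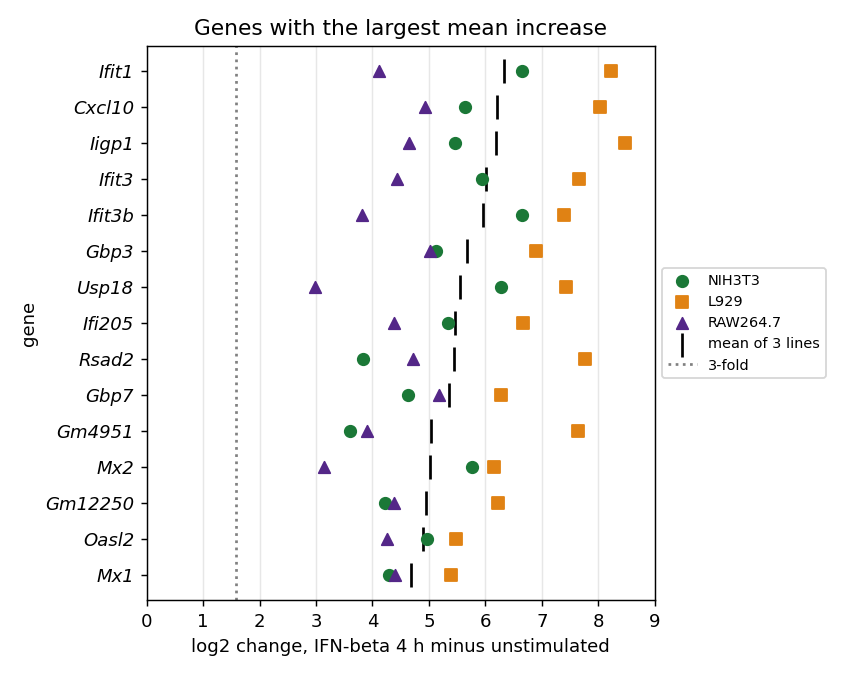
Log2 change (IFN-β 4 h minus unstimulated, horizontal axis) of the 15 genes with the largest mean increase, 1 point per cell line, with the mean of the lines as a bar and 3-fold as a dotted line. L929 has the largest change for each of the 15 genes, up to 8.48 for Iigp1, and each point lies above 3-fold.

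In total 146 genes rose at an adjusted p under 0.05 in limma and 0 fell, and each of the 146 was higher in all 3 lines. Their median mean log2 change was 2.32 and the smallest mean change was 1.83-fold. At an unadjusted p under 0.05 there were 838 genes higher and 254 lower, where chance alone gives 498 in each direction, and the lowest adjusted p of a lower gene was 0.124. No decreases are therefore named. Of the 146 genes, 78 were members of a list fixed beforehand. Genes outside the lists included the receptor transporter Rtp4 (mean log2 change 4.69, adjusted p = 0.0252), the nuclear body protein gene Sp100 (4.28, adjusted p = 0.00385) and Samd9l (3.80, adjusted p = 0.00485). Without the cell line in the model 2 genes passed, and with all probe sets tested together, named or not, 14 passed. Of the 15 genes, 9 lost their call, Ifit1, Cxcl10 and Iigp1 among them, when variances were estimated robustly with a trend, where the adjusted p of Ifit1 was 0.712.

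The 23 gene lists were then compared with all other genes. Among 21 measured antiviral effectors, 16 rose, and 21 rose with p adjusted over the list alone. Beside the Ifit genes and Rsad2, these included the RNA-activated kinase gene Eif2ak2, with a mean log2 change of 2.49. Cmpk2, a mitochondrial nucleotide kinase, had the widest range, with log2 changes of 4.60 in NIH3T3, 0.45 in L929 and 4.20 in RAW264.7 (adjusted p = 0.0671). All 8 guanylate-binding proteins rose (8 over the list alone), from Gbp8 to Gbp3, and Gbp2b ranged from 2.36 in NIH3T3 to 6.06 in L929. Of 4 immunity-related GTPases, 3 rose (3 adjusted over the list alone), namely Iigp1, Gm12250 and Irgm1. Of 11 genes of ISG15 and ubiquitin conjugation, 8 rose (10 adjusted over the list alone), with Usp18, Herc6 at 3.89 and Parp9 at 3.55. In the list of HIN-200 proteins, DNA-binding proteins of the nucleus and cytosol, 3 of 4 rose (3 adjusted over the list alone), namely Ifi205, Ifi202b at 3.40 and Ifi203 at 2.69.

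Of 16 interferon signalling genes, 6 rose (8 adjusted over the list alone). Besides Usp18 these included the transcription factor genes Irf7 (3.96, adjusted p = 0.000545) and Stat2 (3.13, adjusted p = 7.67e-05). The receptor genes Ifnar1 and Ifnar2 did not pass. Among 17 nucleic acid and pathogen sensors 6 rose (11 adjusted over the list alone), led by the viral RNA sensor Ddx58 (3.97), the endosomal receptor Tlr3 (3.49) and Zbp1 (3.48), while Ifih1 ranged from 1.62 in NIH3T3 to 5.68 in L929. In the PARP family, ADP-ribosyltransferases, 5 of 12 rose (8 adjusted over the list alone), with Parp14 at 4.56 and Parp11 at 2.57. Among 11 TRIM proteins 5 rose (8 adjusted over the list alone), with Trim30a at 4.09, Trim21 at 3.37 and Pml at 1.73. Of 7 Schlafen genes 2 rose, Slfn8 at 3.14 and Slfn9 at 2.33. Adjusted over the list alone 7 passed, some of them with little change in NIH3T3. Slfn1 changed by 0.29 in NIH3T3, 1.21 in L929 and 3.55 in RAW264.7. Slfn5 had changes of 0.54 in NIH3T3, 5.21 in L929 and 2.94 in RAW264.7 (adjusted p = 0.104). Of 15 cell death genes 5 rose (7 adjusted over the list alone), among them the death ligand Tnfsf10 (3.77), Xaf1 (3.63) and Daxx (2.25).

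The lists of MHC class I and class II presentation were not tested against each other. Of 16 genes of MHC class I presentation 8 rose (14 adjusted over the list alone), with the peptide transporter subunit Tap1 at a mean log2 change of 2.94, H2-T24 at 2.51 and the immunoproteasome subunit Psmb10 at 2.49. Psmb8 ranged from 0.34 in NIH3T3 to 2.51 in L929. Of 9 MHC class II genes 0 passed over all genes and 0 over the list alone in limma. The class II regulator Ciita had a mean log2 change of 0.36 ± 0.20 (SE), H2-Aa one of 0.23, Ctss one of 0.20, and H2-Ab1 ranged from -0.45 in L929 to 0.41 in RAW264.7. Of 28 chemokines and cytokines 6 rose, with Cxcl10, Tnfsf10 and Il15 (2.51) in the lead. Adjusted over the list alone 19 passed, some of them mainly through 1 line. Among these, Cxcl9, another T cell chemokine, was at 0.83 in NIH3T3, 5.43 in L929 and 1.01 in RAW264.7. Csf1 was at 0.50, 0.42 and 3.11 in the same order. None of the 16 NF-kB targets passed over all genes or over the list alone (0 and 0). Nos2, Bcl3 and Tnfaip3 had mean log2 changes of 0.70, 0.39 and 0.39.

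With camera at a preset correlation of 0.01, 16 lists were shifted up and 4 down. The 16 were the 13 lists named above of which some genes rose, the NF-kB targets (adjusted p = 0.00888), the immediate early and stress genes (adjusted p = 0.0317) and the macrophage markers (adjusted p = 0.0108). None of the 20 calls held with an estimated correlation, where the adjusted p-values ran from 0.0783 for 10 of the lists to 0.487 for immediate early and stress genes. Among the latter, Atf3, Hmox1 and Junb had mean log2 changes of 0.76, 0.61 and 0.51, and 0 of 17 members passed alone. Correlation between genes does not account for every lost call. It was estimated at -0.000285 for interferon signalling and -0.0343 for chemokines and cytokines, both below the preset. Their adjusted camera p still went from 2.4e-15 and 1.34e-20 to 0.0783. Unadjusted, 11 lists had a camera p under 0.05 with an estimated correlation. The lists shifted down were housekeeping (median of the mean changes -0.26), cell cycle (-0.15), fibroblast markers (-0.13) and cholesterol synthesis and uptake (-0.12), with adjusted p-values of 0.189, 0.126, 0.153 and 0.279 with an estimated correlation. No member of these 4 lists passed alone. Cdc6, Myc, Bub1 and Ccnd1 of the cell cycle list had mean log2 changes of -0.40, 0.26, -0.26 and -0.05. In the cholesterol list those of Lss, Insig1, Fdps and Mvd were -0.42, -0.39, -0.21 and -0.15. Actb, Ppia, Rplp0 and Pgk1, the brightest of the 11 housekeeping genes, had log2 changes of -0.79, -0.78, -0.57 and -0.46 in NIH3T3, -0.35, -0.03, -0.15 and -0.18 in L929, and 0.04, -0.08, -0.18 and -0.14 in RAW264.7. The MHC class II, epithelial and lymphocyte lists were not called (adjusted p = 0.298, 0.0991 and 0.316).

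**Figure D2:**
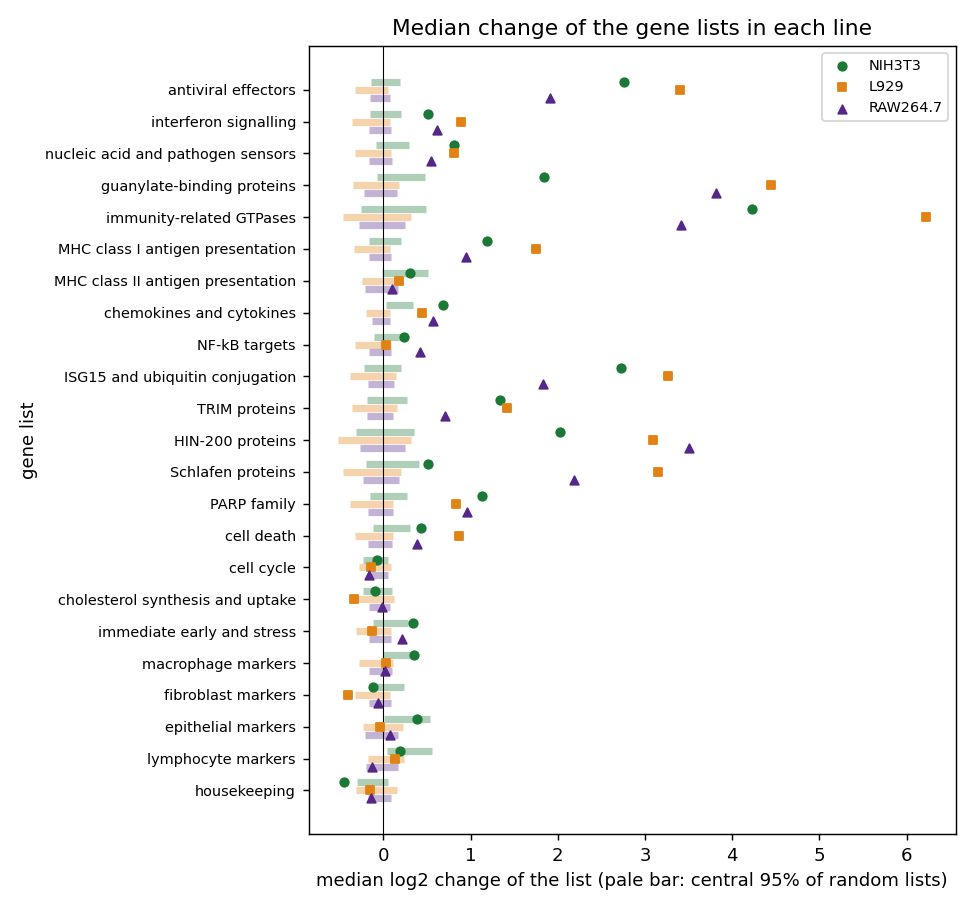
Median log2 change (horizontal axis) of each gene list in each cell line, with the central 95% of 10000 random lists of the same size and expression as a pale bar. The largest medians are those of the immunity-related GTPases in NIH3T3 (4.23) and L929 (6.22) and of the guanylate-binding proteins in RAW264.7 (3.82), and MHC class II lies within the bars.

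Within each line, the change of 2 arrays was counted against the 3-fold rule of the series' design text. In each line 3 of the 10 genes named had an unstimulated level below the lower quartile of their array, Ifit3b, Mx2 and Iigp1 in NIH3T3, Iigp1, Gm4951 and Ifit3b in L929, and Iigp1, Ifi209 and Tnfsf10 in RAW264.7, and folds and ranks from such low levels are approximate. In NIH3T3 95 genes were at least 3-fold higher with IFN-β and 8 were lower. Ifit3b and Ifit1 were both 99.9-fold higher, Usp18 77.2-fold, Ifit3 61.5-fold and the GTPase gene Mx2 54.7-fold. Rtp4, Cxcl10, Iigp1, Ifi205 and Gbp3 followed, with folds from 50.3 for Rtp4 to 34.8 for Gbp3. The largest decreases were those of Ubxn2a (log2 change -2.73), Zfp617 (-2.47), Macroh2a2 (-2.30), Macrod2 (-2.16) and Pisd-ps2 (-2.13), and in L929 and RAW264.7 each of the 5 differed by less than 1 on the log2 scale. A second probe set of Ubxn2a was higher in NIH3T3, by 0.52, and the other probe sets of Macrod2 ranged from -0.86 to 0.97. With each array centred on its median, 75 genes were higher and 14 lower in NIH3T3.

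In L929 178 genes were at least 3-fold higher and 2 lower. Iigp1 was 357-fold higher, Ifit1 299-fold, Cxcl10 261-fold, Rsad2 217-fold and Ifit3 201-fold. Gm4951, Usp18, Ifit3b, Rtp4 and Gbp3 were between 199.6-fold and 118.7-fold higher. The 2 lower genes were Usp17ld, a deubiquitinase gene, with a log2 change of -4.44, and the retroviral restriction gene Fv1, with -1.83. In RAW264.7 123 genes were at least 3-fold higher and 0 lower, and at 2-fold 14 were lower. Ifi202b was 41.9-fold higher, Gbp7 36.1-fold, Gbp2b 35.1-fold, Gbp3 32.3-fold and Cxcl10 30.5-fold. Rsad2, Iigp1, Ifi209, Ifit3 and Tnfsf10 were between 26.2-fold and 21.3-fold higher.

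Against random lists matched on expression, 14 lists lay above the central 95% in NIH3T3, 13 in L929 and 15 in RAW264.7. The 13 lists of antiviral effectors, interferon signalling, sensors, guanylate-binding proteins, immunity-related GTPases, MHC class I, chemokines, ISG15 conjugation, TRIM, HIN-200, Schlafen, PARP and cell death genes lay above it in each line. NF-kB targets stood above all 10000 random lists in RAW264.7, with a median log2 change of 0.42, at percentile 94.8 in NIH3T3 and at 92.7 in L929. Immediate early and stress genes lay at percentiles of 99.3 in NIH3T3, 42.3 in L929 and 99.97 in RAW264.7. In L929 fibroblast markers were low at percentile 0.24, with Col1a1 at -1.22 and Col1a2 at -1.09, and cholesterol genes at 1.37, with Lss at -1.16 and Insig1 at -0.95. In NIH3T3 Col1a1 and Col1a2 had changes of 0.27 and 0.45, and these differences between lines were not tested. Cell cycle genes were low in RAW264.7, at percentile 1.04 with a median log2 change of -0.16, but at 10.9 with the mean over probe sets and at 4.19 with the mean of the list, both within the central 95%. Housekeeping genes were low in NIH3T3, below all 10000 random lists, on the array with the shifted scale, and their median log2 change of -0.46 was -0.18 after quantile normalization.

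The lists of genes at least 3-fold higher overlapped between lines. Any line had 220 such genes, counted here through 1 single-gene probe set each, where the series' design text states 225. By probe sets the count was 916, and the genes behind 220 and 225 need not be the same. All 3 lines shared 62 genes, Ifit1, Cxcl10, Iigp1, Mx1, Oasl2 and Stat2 among them. NIH3T3 and L929 shared 79 genes against 0.848 for independent lists, NIH3T3 and RAW264.7 68 against 0.586, and L929 and RAW264.7 91 against 1.10. L929 alone had 70 genes, RAW264.7 alone 26 and NIH3T3 alone 10. Cxcl9 was among the genes of L929 alone, and Csf1, a macrophage growth factor, among those of RAW264.7 alone. The Csf1 level in stimulated RAW264.7, 6.62, stayed below those in unstimulated NIH3T3 and L929, 9.02 and 10.37. Without the NIH3T3 arrays, an alternative added after the data were seen, 210 genes were higher in either of the other lines and 91 in both. Each of the 62 shared genes was among the 146 called across the lines.

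**Figure D3:**
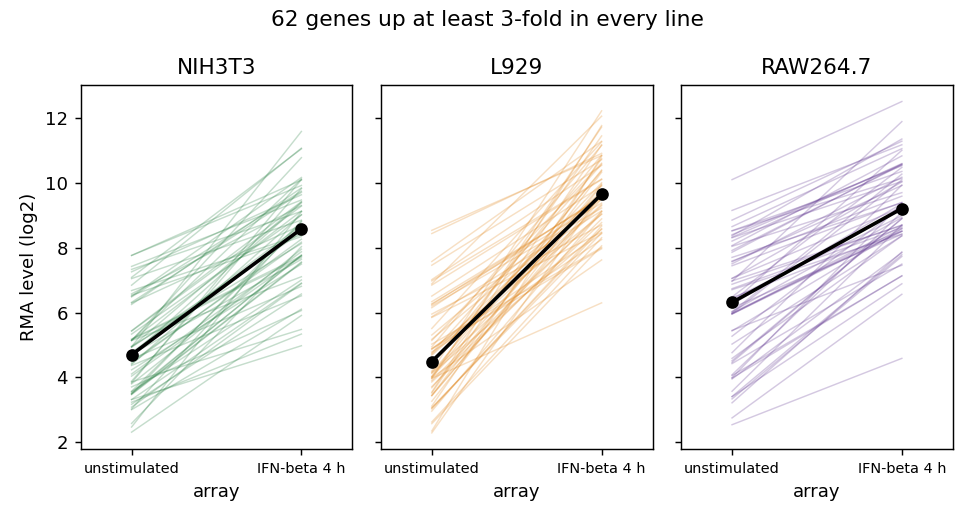
Log2 RMA level (vertical axis) of the 62 genes at least 3-fold higher in every line, 1 line per gene from the unstimulated to the stimulated array, with the median in black. The unstimulated median is 6.31 in RAW264.7, 4.70 in NIH3T3 and 4.49 in L929, and the stimulated medians are 9.21, 8.58 and 9.66.

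The 62 shared genes changed most in L929. Their median fold was 12.4 in NIH3T3, 34.4 in L929 and 6.56 in RAW264.7. The change was the largest of the 3 in L929 for 52 genes and the smallest in RAW264.7 for 42.

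The response of RAW264.7 was tested against that of the fibroblast lines with an interaction term. RAW264.7 had 1 pair of arrays. With 1 residual degree of freedom the fit gave every gene the same standard error of 0.49, from the 2 fibroblast lines pooled over all genes. The p-values thus assume that RAW264.7 varies like those lines and that induced genes vary like all others. Between the fibroblast lines Sp100 differed more, with changes of 4.07 in NIH3T3 and 6.37 in L929, while Csf1 changed by 0.50 and 0.42. The p-values also do not separate the line from the variation of 1 pair. A larger change in RAW264.7 was found for the membrane protein gene Ms4a4c, with a log2 change of 3.67 against a fibroblast mean of 0.63 (difference 3.04 ± 0.49, SE, adjusted p = 2.45e-06), and for Ifi202b, with 5.39 against 2.40 (adjusted p = 4.21e-06). The same held for Slfn1 (difference 2.80), Csf1 (2.65), the itaconate-producing enzyme gene Acod1 (2.60), the Fc receptor gene Fcgr4 (2.53) and BC147527 (2.64). Usp17ld differed by 3.53, through its decrease in L929. BC147527 changed by -0.24 in NIH3T3, 2.60 in L929 and 3.83 in RAW264.7, so its difference came more from NIH3T3 than from L929. Unstimulated levels of Ms4a4c were 2.95 in RAW264.7, 2.23 in NIH3T3 and 2.48 in L929. Each is below the lower quartile of its array (3.40, 3.34 and 3.36), so the size of its difference is approximate. A smaller change in RAW264.7 was found for Rtp4, with 1.33 against a fibroblast mean of 6.37 (difference -5.04, adjusted p = 4.3e-20), and for Usp18, with 2.98 against 6.85 (difference -3.86, adjusted p = 5.5e-11). Ifit1, Ifit3b, Samd9l, Sp100, Mx2 and Irgm1 followed, with differences from -3.31 for Ifit1 to -2.79 for Irgm1. Unstimulated levels of Rtp4 were 9.71 in RAW264.7, 4.99 in NIH3T3 and 4.01 in L929, and its stimulated levels were 11.03, 10.64 and 11.09. A larger change did not always mean a higher level. In the same order of lines, Csf1 was at 3.52, 9.02 and 10.37 unstimulated and 6.62, 9.51 and 10.79 stimulated. Ifi202b was at 3.99, 7.77 and 8.44, then 9.38, 10.09 and 10.92, while Acod1 began higher in RAW264.7, at 8.71, 4.38 and 4.12.

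In all, 16 genes had a larger and 31 a smaller change in RAW264.7 at an adjusted p under 0.05, and 27 of the 47 were also called across the lines. With all probe sets tested together 3 probe sets had a larger and 1 a smaller change, and each of the 16 genes named here lost its call. After quantile normalization 4 genes had a larger and 6 a smaller change, and Usp17ld, Slfn1, BC147527, Fcgr4, Samd9l, Sp100 and Irgm1 were no longer among them.

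**Figure D4:**
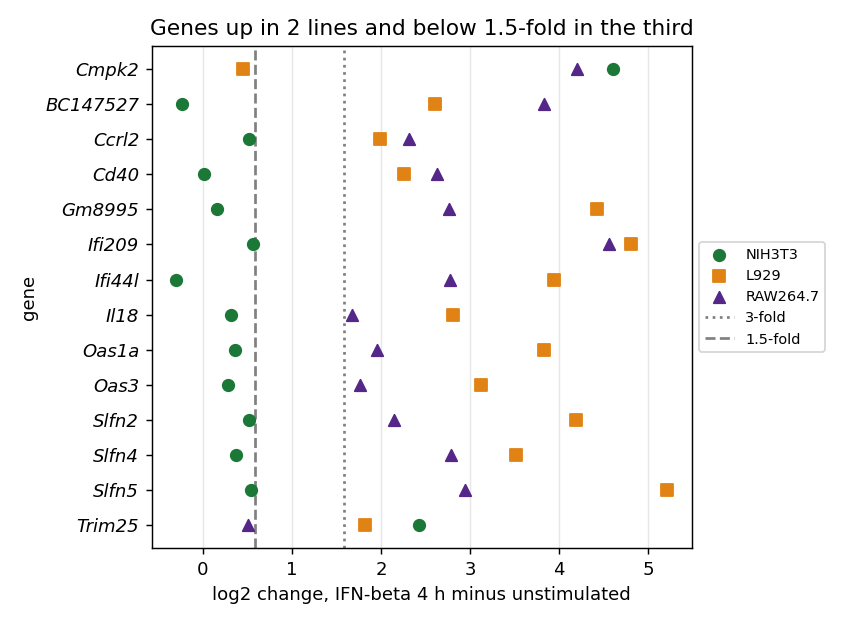
Log2 change (horizontal axis) in each line of the genes at least 3-fold higher in 2 lines and below 1.5-fold in the remaining one, 1 point per line, a selection made after the values were seen. Of the 14 genes, 12 were below 1.5-fold in NIH3T3, Cmpk2 was so in L929 and Trim25 in RAW264.7.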

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

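All tests of explanations in this part were chosen after the results were seen.

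RAW264.7 differed from the fibroblast lines by the interaction test, with 16 genes of larger and 31 of smaller change. RAW264.7 had 1 pair of arrays, and the spread came from the 2 fibroblast lines, pooled over all genes. A difference of the line and the variation of a single pair were therefore not separated. Usp17ld went in opposite directions, with a log2 change of -4.44 in L929 and 1.55 in RAW264.7, and rests on 1 probe set. Outside the genes analysed, 24 probe sets that name several genes and 20 that name none were at least 3-fold higher in all 3 lines.

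The first pattern is the smaller change in RAW264.7 of the 62 genes shared by all lines, with a median difference from L929 of -1.80 on the log2 scale. Their unstimulated level was higher in RAW264.7 than in L929 by a median of 1.17 (95% bootstrap interval 0.81 to 1.75 over genes), and their stimulated level lower, at -0.35 (-0.72 to -0.10), while against NIH3T3 both were higher, by 1.18 (0.90 to 1.83) and 0.80 (0.24 to 1.19), which divides the differences and does not test their cause. Stimulated RNA mixed into the unstimulated RAW264.7 sample, as a part of the cause, cannot be told apart from a higher level in these cells: at the share allowed by the 10th largest RAW264.7 change, 4.69%, the observed level lay above such a mixture by a median of 0.20 (-0.26 to 0.50), and at the 2.39% allowed by the largest, that of Ifi202b, by 0.58 (0.13 to 0.86). As the whole cause it stays open too. At 4.69%, 20 of the 62 genes lay over 2-fold above the mixture (95% interval 20.9% to 45.3%) and 5 over 2-fold below it (2.67% to 17.8%). Unstimulated NIH3T3 lay over 2-fold above L929 for 4 genes (1.79% to 15.7%) and below it for 7 (4.66% to 21.9%). The interval for the 20 genes lies above those for the 5 and the 4 but overlaps that for the 7. The test asked for an interval above all of these, so it did not decide. The difference in cell type and any other difference between the lines' cultures stay open as well, as untested.

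The second pattern is the set of 12 genes at least 3-fold higher in L929 and RAW264.7 and below 1.5-fold in NIH3T3, among the 91 genes higher in both: BC147527, Ccrl2, Cd40, Gm8995, Ifi209, Ifi44l, Il18, Oas1a, Oas3, Slfn2, Slfn4 and Slfn5. Their median unstimulated levels were 4.12 in NIH3T3, 4.15 in L929 and 6.76 in RAW264.7. Stimulated, the medians were 4.36 in NIH3T3 and 8.21 in L929. The scale of the stimulated NIH3T3 array is argued against as the whole cause: it would have to lower a change by at least 1 on the log2 scale, and the lowest median change over 10 equal groups of all genes by level was -0.12. Of the 91 genes, 62 were at least 3-fold higher in NIH3T3 too. Their median fold was 12.4 in NIH3T3 and 6.56 in RAW264.7, and the change was the smallest in RAW264.7 for 42 and in NIH3T3 for 20. These folds do not decide whether the response was weaker in NIH3T3 than in RAW264.7 for all genes alike. The 62 genes were chosen in part for a rise of at least 3-fold in NIH3T3. Their stimulated level was higher in RAW264.7 than in NIH3T3 by a median of 0.80, and their unstimulated level by 1.18. Against L929, with a median fold of 34.4, a weaker response in NIH3T3 stays open, since with 1 pair of arrays per line the spread of induced genes is not known. A difference of the lines in these genes and sequence variants under the probes stay open, as untested.

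The third pattern is on the stimulated NIH3T3 array, where the 157 genes at a level of 11 or more in all unstimulated lines had a median log2 change of -0.31, with 152 lower, while genes below a level of 5 had one of 0.29. Of the same genes 107 were lower in L929 and 111 in RAW264.7, but by at most 0.10 in size (median). This argues against an effect of IFN-β of the size seen in NIH3T3 being shared by the lines. The 229 unnamed probe sets at a level of 11 or more moved by -0.28 (95% bootstrap interval -0.32 to -0.26), so the shift followed level whether or not a probe set names a gene, consistent with a scale difference of that array. An effect of IFN-β in NIH3T3 alone was not tested.

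The 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05. The real split called 146 genes, only 1 of the 10 splits called as many, and the highest other count was 1.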

How the results depend on the processing

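Alternatives were planned before the data were examined, except leaving out the NIH3T3 arrays from the overlap. For the genes named across lines, each kept its direction under each alternative, and calls were lost for 10 of 15 with all probe sets, 9 with robust variances and a trend, and 13 without the block; for RAW264.7 against the fibroblast lines calls were lost for all 16 with all probe sets, 7 after quantile normalization and 2 with robust variances and a trend. None reversed.

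Counting probe sets in place of genes gave 394 higher and 243 lower in NIH3T3, 564 and 168 in L929, 264 and 70 in RAW264.7, 916 higher in any line, 111 in all, and 140, 118 and 159 shared by NIH3T3 with L929, NIH3T3 with RAW264.7 and L929 with RAW264.7. At 2-fold the counts were 345 and 57, 314 and 75, 228 and 14, then 588, 109, 144, 115 and 149. At 5-fold they were 62 and 2 in NIH3T3, 115 and 1 in L929, 67 higher in RAW264.7, 131 in any line, 34 in all, 35 in NIH3T3 with RAW264.7 and 56 in L929 with RAW264.7. The lower NIH3T3 genes numbered 5 with the mean over probe sets and 14 with centred arrays. These follow from what is counted; the causes of the changes below were not tested, apart from the block.

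Across lines, 146 genes became 14 with all probe sets and 2 without the replicate block, where differences between lines enter the error. Leaving out 1 line gave from 116 to 218 higher genes and from 0 to 5 lower, the 5 without RAW264.7. For RAW264.7, 16 higher and 31 lower became 3 and 1 with all probe sets and 4 and 6 after quantile normalization, and 9 higher with robust variances and a trend. With an estimated correlation 0 lists were called up and 0 down. Leaving out 1 line gave from 14 to 16 lists up and from 2 to 4 down, the 2 without NIH3T3 or without L929. The 1 list below the random range in RAW264.7 became 0 with the mean over probe sets and 0 with the mean of the list.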

Other observations

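The genes of this part were chosen after their values were seen. Among genes called across the lines but outside the lists were the helicase-like Ddx60 (mean log2 change 4.24), Phf11d (4.21) and Trim30d (3.74). Cd274, the gene of PD-L1, rose by a mean log2 change of 2.12, Lgals9 by 2.31 and Clec2d by 3.15. In L929 alone, Mpeg1, a pore-forming protein of macrophages, had a log2 change of 4.18 and Il6 one of 3.96, against 0.63 and 1.13 in NIH3T3, a difference that was not tested. In RAW264.7 alone, complement factor B (Cfb) had a change of 2.73, the activation marker Cd69 one of 2.53 and the Fc receptor gene Fcgr1 one of 2.09. In the limma interaction test of RAW264.7 against the fibroblast lines the adjusted p was 0.0393 for Cfb, 0.00799 for Cd69 and 0.0289 for Fcgr1, but 0.192, 0.22 and 0.0965 after quantile normalization and 0.618, 0.681 and 0.583 with all probe sets, so the calls did not hold. Over the settings tried it ranged from 0.0359 to 0.618 for Cfb, from 0.00202 to 0.681 for Cd69 and from 0.0264 to 0.583 for Fcgr1.

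Genes at least 3-fold higher in any line often lay next to each other among the measured genes ordered by position in GRCm38. The 220 genes formed 53 adjacent pairs, against a mean of 2.42 and a highest count of 9 in 10000 random sets (permutation p = 0.0001, the smallest these permutations can give). Pairs whose names have different stems numbered 14, against a mean of 2.07 and a highest count of 10, and some of these are related genes under other names. They included Parp14, Dtx3l and Parp9 in a row, with log2 changes in L929 of 6.43, 4.88 and 4.65, and Psmb9, Tap1 and Psmb8. Rsad2 and Cmpk2 are neighbours too. In L929 Rsad2 changed by 7.76 and Cmpk2 by 0.45, while in NIH3T3 the changes were 3.83 and 4.60 and in RAW264.7 4.71 and 4.20.

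Unnamed probe sets were noisier than genes, with a robust SD of the RAW264.7 change of 0.35 against 0.22 for probe sets of a single gene. The most extreme had a log2 change of 10.10 in RAW264.7, with -1.85 in NIH3T3 and -0.08 in L929.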
